A study of Mus musculus with 2 samples.

How the data were processed

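H3K4me3, the trimethylation of lysine 4 of histone H3 that marks active and poised promoters, was mapped by chromatin immunoprecipitation and sequencing in the facial prominence of B6NCrl mouse embryos at embryonic day 12.5. The facial prominences are the swellings around the mouth opening that grow into the jaws, palate and midface. The series holds 1 group with 2 biological replicates, each a pool of dissected tissue from male and female embryos: 120 embryos in replicate 1 and 88 in replicate 2, per the labels. No other tissue, stage, genotype or treatment was in the series, so the comparisons are between the replicates, between peak lists and between classes of genes within this tissue.

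The deposited data are 4 lists of peaks on the mm10 assembly, per the file headers and the notes deposited with them. The authors called peaks in each replicate against that replicate's own control, and again on both replicates pooled with both controls. A further list of replicated peaks was derived by the authors from the pooled list and both replicate lists, and the rule for replication is not given in the sources used here. Testing the lists showed that each of the 22943 replicated peaks is a peak of the pooled list with the same coordinates and values. The aligner and the peak caller are not given in the sources used here. For each peak the authors deposited a fold enrichment, taken as a linear ratio of the immunoprecipitated signal over the control. They also deposited −log10 p-values and −log10 q-values for each peak. The deposited notes name the narrowPeak format, and these meanings and scales were assumed from the convention of that format, since the notes do not describe the columns. Every fold enrichment below is the authors' value for a peak of the list named. The smallest −log10 p was 2.00 in replicate 1 and 2.05 in replicate 2, and the smallest −log10 q was 0.169 and 0.244, so the lists reach down to weak peaks. They contain no read counts, so the sequencing depth is unknown and no counting interval is given for any value. How depth differed between the replicates could not be taken into account.

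Peaks were compared with the GRCm38 reference genome, whose chromosome 1 has the mm10 length of 195471971 bp, and with GENCODE mouse release 21 of the M series. Protein-coding genes on the assembled nuclear chromosomes were combined by symbol, which gave 21829 genes with 54361 annotated starts. A gene had a peak when a peak overlapped 1000 bp either side of any start of its protein-coding transcripts. A peak in such a window can belong to a neighbouring gene, and genes with near-identical copies elsewhere in the genome are uncertain where reads could not be placed. Domains were made by merging peaks of a list separated by at most 1000 bp, and a gene took the widest domain that overlapped its window. Genes without a domain were given a width of 0. Widths and orders of genes are those of the replicated list unless a replicate is named. Widths per replicate came from that replicate's own list, and means are given with the SD of the 2 replicates. A promoter window of 1000 bp was CpG-rich with a CpG observed-to-expected ratio of at least 0.6 and a GC content of at least 50%. A gene and its promoter counted as CpG-rich when any of its starts had such a window. The peak could lie at another start of the gene, so these shares are per gene.

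A peak was counted as found in another list when at least 50% of its length was covered there. Agreement of strength was given by Spearman's rho and Pearson's r of log2 fold enrichment across replicated peaks, taking for each the highest overlapping peak of each replicate. These are correlations across peaks, which are not independent replicates, and no p-value was computed for them. Chance overlap was estimated by placing peaks at random within their chromosomes, 10 times for the replicate overlap and 100 times for the annotation classes.

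In all, 18 gene lists were tested: 17 written from textbook knowledge before the data were examined, with 343 genes, and the olfactory receptors taken by symbol. They cover facial mesenchyme transcription factors, arch patterning by Dlx and Hand genes, facial signalling, oral and surface epithelium, orofacial cleft genes, cartilage and bone, skeletal muscle, the Hox clusters, transcription factors of other organs, forebrain and eye transcription factors, neurons and glia, endothelium, blood cells, heart, liver, germ line and housekeeping genes. A gene may stand in several lists. The share of each list with a peak was compared with all other protein-coding genes by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 18 lists and a threshold of 0.05. The same share, and the median domain width, were placed among 10000 random lists of equal size matched on the decile of promoter CpG ratio. Domain widths of facial mesenchyme and other-organ transcription factors were compared by a two-sided permutation test of list membership with 100000 resamples. All of these tests are across genes within 1 tissue. Genes are not replicates, and the p-values describe these 2 pools of embryos.

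The genes named were chosen by a rule fixed before the data were examined. It takes the 20 widest promoter domains present in both replicates, up to 4 members of each list with the widest domains and up to 4 without a peak in alphabetical order, any Hox gene, the 5 strongest replicated peaks outside protein-coding start windows, and for each replicate the 5 genes with the strongest start peak that the other replicate lacked. Xist, Twist1, Alx4, Msx1, Dlx5, Hand2, Hoxa2 and Actb are given in full. Alternatives tried were another overlap requirement, stricter peak thresholds (−log10 q of at least 5, or fold enrichment of at least 3), each replicate's list alone, the pooled list, a window of 2500 bp, a peak on the start itself, the 5′-most start alone, CpG-rich genes alone, and merging gaps of 0 or 3000 bp. Peaks on unplaced scaffolds were left out of the gene comparisons.

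The functions were tested on simulated peaks at 5030 isolated genes. All domains were recovered with the right width. A list of 200 genes given a higher share of peaks was called by Fisher's exact test (p = 4.84e-25), and 1 of 100 random lists gave an exact p below 0.05. In the simulated replicates, 70.0% of peaks were made to overlap and 70.0% were found. Computations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9, and minimap2 2.31 for the search for promoter copies in the closing section.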

Results

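H3K4me3 peaks were analysed in 2 pools of mouse facial prominence at embryonic day 12.5. Replicate 1 had 29966 peaks covering 34.8 Mb, with a median width of 852 bp and a median fold enrichment of 8.78. Replicate 2 had 31719 peaks covering 36.1 Mb, with a median width of 761 bp and a median fold enrichment of 7.16. The pooled list held 32536 peaks and the replicated list 22943 peaks, the latter covering 37.5 Mb with a median width of 1457 bp. Sequencing depth is unknown, since the lists hold no counts.

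The first question was how far the replicates shared their peaks. Nearly every strong peak was present in both pools of embryos. Of the peaks with a fold enrichment of at least 10, 99.99% of those in replicate 1 and 99.97% of those in replicate 2 were found in the other replicate. Over all peaks, 75.5% of replicate 1 peaks were found in replicate 2 and 70.6% of replicate 2 peaks in replicate 1, against 1.43% and 1.41% for randomly placed peaks. Peaks found in the other replicate had a median width of 1306 bp in replicate 1 and 1348 bp in replicate 2, and those not found had medians of 231 and 227 bp. Across the 21619 replicated peaks that overlapped a peak of both lists, fold enrichment had a Spearman's rho of 0.934 and a Pearson's r of 0.95 on the log2 scale. These peaks lie within 2 samples and are not independent, and only 2 peaks had the same coordinates in both lists.

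**Figure D1:**
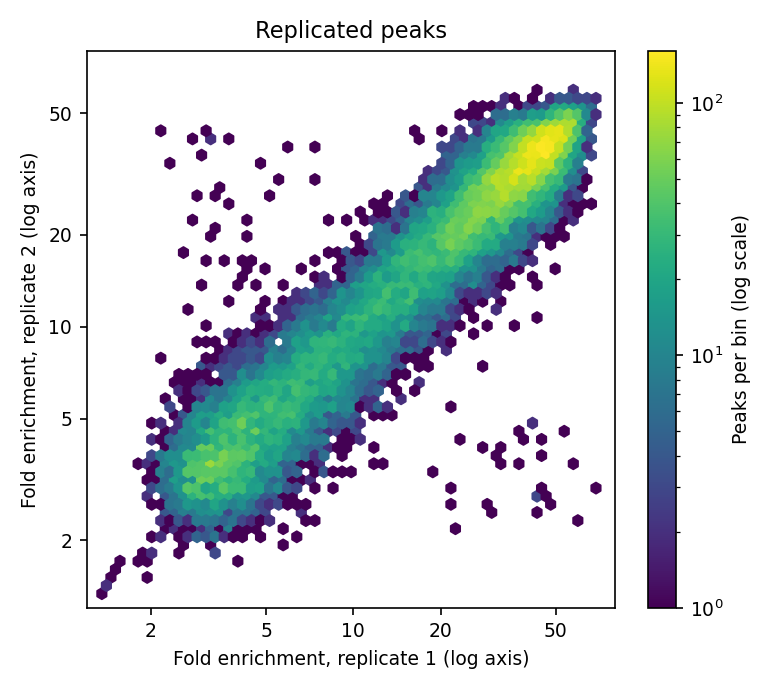
Fold enrichment of replicated peaks in replicate 1 (x axis) and replicate 2 (y axis), both on log axes, with colour giving the number of peaks per bin on a log scale. The 21619 peaks lie along the diagonal (Spearman's rho of 0.934), with scattered peaks strong in 1 replicate and weak in the other.

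At the level of genes the replicates were closer than at the level of peaks. A protein-coding start peak was present in both replicates for 14264 genes, in replicate 1 only for 150 and in replicate 2 only for 163. The genes with the strongest start peak seen in replicate 1 only were Tnnc1, which encodes the troponin C of slow muscle and heart, at a fold enrichment of 39.2, Vpreb1, a pre-B-cell receptor component, at 32.8, Hrc, a calcium-binding protein of the sarcoplasmic reticulum, at 27.6, Igfn1 at 13.3 and Nlrp6 at 9.66. In replicate 2 only they were Oscar, an osteoclast receptor, at 38.6, B3gnt4 at 27.2, 1700017N19Rik at 25.5, the homeobox gene Dbx2 at 11.0, and Rs1, the retinoschisin gene, at 10.8. For all 10 of these genes the replicate without a start peak had a peak within 2000 bp of a start. The nearest lay 1015 bp from a Dbx2 start and the farthest 1161 bp from a Tnnc1 start, just outside the window. Of the 10, 9 had a peak in the replicated list, B3gnt4 being the exception.

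The replicated list kept the wide, strong, promoter-bound part of the pooled list. It held 70.5% of the pooled peaks. Kept peaks had a median fold enrichment of 20.8 and a median width of 1457 bp, and 64.0% overlapped a protein-coding start window. The 9593 peaks removed had a median fold enrichment of 2.55 and a median width of 234 bp, and 16.1% overlapped such a window. At least 50% of the length was covered in both replicates for 88.8% of kept peaks and for none of the removed peaks.

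Where H3K4me3 lay in the genome was compared with random placement. On the assembled chromosomes 64.0% of replicated peaks overlapped a protein-coding start window, against 4.59% ± 0.14 (SD, 100 random placements), which is 14.0 times the random share. Starts of other annotated transcripts held a further 8.57% of peaks (random 6.09%) and exons 4.13% (random 2.89%). Introns held 10.7% of peaks and intergenic sequence 12.6%, below their random shares of 37.9% and 48.5%. Peaks at protein-coding starts had a median width of 1935 bp, and those in introns 566 bp.

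The strongest replicated peak outside protein-coding start windows, with a fold enrichment of 66.1, covered the start of Malat1, an abundant nuclear long non-coding RNA, at chromosome 19, 5796149 to 5804197. The next, at 63.8, covered the start of a transcript of Baz2a without a coding sequence at chromosome 10, 128096350 to 128098728, 3567 bp from the nearest protein-coding start. A peak at the processed transcript 1810026B05Rik near Chd2, at chromosome 7, 73555948 to 73559800, reached 61.8. A peak at the non-coding RNA gene Gm8066 near Gigyf1, at chromosome 5, 137509719 to 137512585, reached 58.8. An intronic peak at chromosome 2, 90678398 to 90680809, 1183 bp from a start of the nucleoporin gene Nup160, reached 58.9. Xist, the non-coding RNA of X inactivation, carried a domain of 3651 bp at its 5′ end at chromosome X, 103480090 to 103483740, with a fold enrichment of 14.7. Its width was 3558 bp ± 88.4 (SD, n = 2) in the replicate lists of these mixed-sex pools.

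Of the 21829 protein-coding genes, 14324 (65.6%) had a replicated peak at a start. The share was 66.0% in replicate 1 and 66.1% in replicate 2. Genes with a CpG-rich promoter had a peak at a start in 10816 of 10932 cases (98.9%). Other genes had one in 3508 of 10897 cases (32.2%), an odds ratio of 196 (Fisher's exact test, two-sided, p below 1e-300). The replicates gave 99.0% and 99.0% for CpG-rich promoters and 33.0% and 33.1% for the others, so the gap was far larger than the spread between them. Domains at CpG-rich promoters had a median width of 2370 bp, and those at other promoters 1504 bp.

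Which regulators of the developing face carried the mark was asked through gene lists. All 27 facial mesenchyme transcription factors had a start peak (adjusted exact p = 4.9e-05), as did all 14 Dlx, Hand and related arch patterning genes (adjusted exact p = 0.00733), all 27 facial signalling genes (adjusted exact p = 4.9e-05) and all 33 orofacial cleft genes (adjusted exact p = 5.07e-06), against 65.6% of other genes. Both replicates gave the same complete shares for these 4 lists. The 20 housekeeping genes also all had a peak (adjusted exact p = 0.00105). Among CpG-rich genes alone nearly every promoter had a peak, and none of these 5 lists then passed the test (each adjusted exact p = 1). Against random lists matched on promoter CpG ratio, the share of the cleft list stood at the 99.8th percentile, and that of the facial mesenchyme factors at the 83.4th. Both lists were complete, so these are the highest percentiles each could reach, and they depend on how many matched lists were also complete. The mean matched shares were 90.4% for the cleft list and 96.5% for the facial mesenchyme factors, so the percentiles do not rank these lists.

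Facial mesenchyme transcription factors carried some of the widest domains. Six1 and Six2, homeobox regulators of craniofacial and kidney progenitors, had domains of 16613 and 16420 bp, and Satb2, a chromatin organiser required for palate and jaw, one of 16003 bp. Six2 was 16079 bp ± 427 (SD, n = 2) in the replicate lists, while Six1 was 10221 bp in replicate 1 and 16575 bp in replicate 2. Twist1, the basic helix-loop-helix factor mutated in Saethre-Chotzen syndrome, lay wholly inside a domain of 13638 bp at chromosome 12, 33955517 to 33969154, with a fold enrichment of 54.1 and a replicate width of 11338 bp ± 3133 (SD, n = 2). Msx1, required for tooth and palate development, lay inside a domain of 12385 bp at chromosome 5, 37816947 to 37829331, with a fold enrichment of 36.7 and a replicate width of 12219 bp ± 196 (SD, n = 2). Alx4, a homeobox factor of the frontonasal skeleton, had a domain of 8382 bp over its 5′ part at chromosome 2, 93641542 to 93649923, with a fold enrichment of 37.6 (40.1 in replicate 1 and 23.9 in replicate 2) and a replicate width of 9149 bp ± 312 (SD, n = 2).

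In the arch patterning list, Dlx1 and Dlx2 shared a domain of 21294 bp at chromosome 2, 71525928 to 71547221, that spanned both genes and the sequence between them. The replicates differed here. For Dlx1 the width was 10528 bp in replicate 1 and 21298 bp in replicate 2, because a gap between peaks exceeded 1000 bp in replicate 1. Pou3f3 had a domain of 16671 bp and Dlx6 one of 13663 bp. Hand2, which specifies the distal part of the mandibular arch, lay inside a domain of 11538 bp at chromosome 8, 57317966 to 57329503, with a fold enrichment of 21.6 and a replicate width of 11691 bp ± 938 (SD, n = 2). Dlx5 lay inside one of 9163 bp at chromosome 6, 6873583 to 6882745, with a fold enrichment of 36.6 and a replicate width of 8999 bp ± 98.3 (SD, n = 2).

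Among the signalling genes the widest domains belonged to Ptch1, the Hedgehog receptor (16041 bp), Wnt5a (11980 bp), Pdgfra, a receptor of neural crest cells (11180 bp), and Fgfr2 (8791 bp). The cleft genes were led by Ptch1, Satb2, the transcriptional regulator Mn1 (12935 bp) and Msx1. In the housekeeping list Rpl13a had 7354 bp and Polr2a 5627 bp. Rpl13a was 3617 bp in replicate 1 and 8649 bp in replicate 2, and Polr2a 5471 and 6196 bp. Actb, the cytoplasmic actin gene, had a domain of 3920 bp at chromosome 5, 142903765 to 142907684, with a fold enrichment of 54.1, while the replicate lists gave 6010 bp ± 740 (SD, n = 2).

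**Figure D2:**
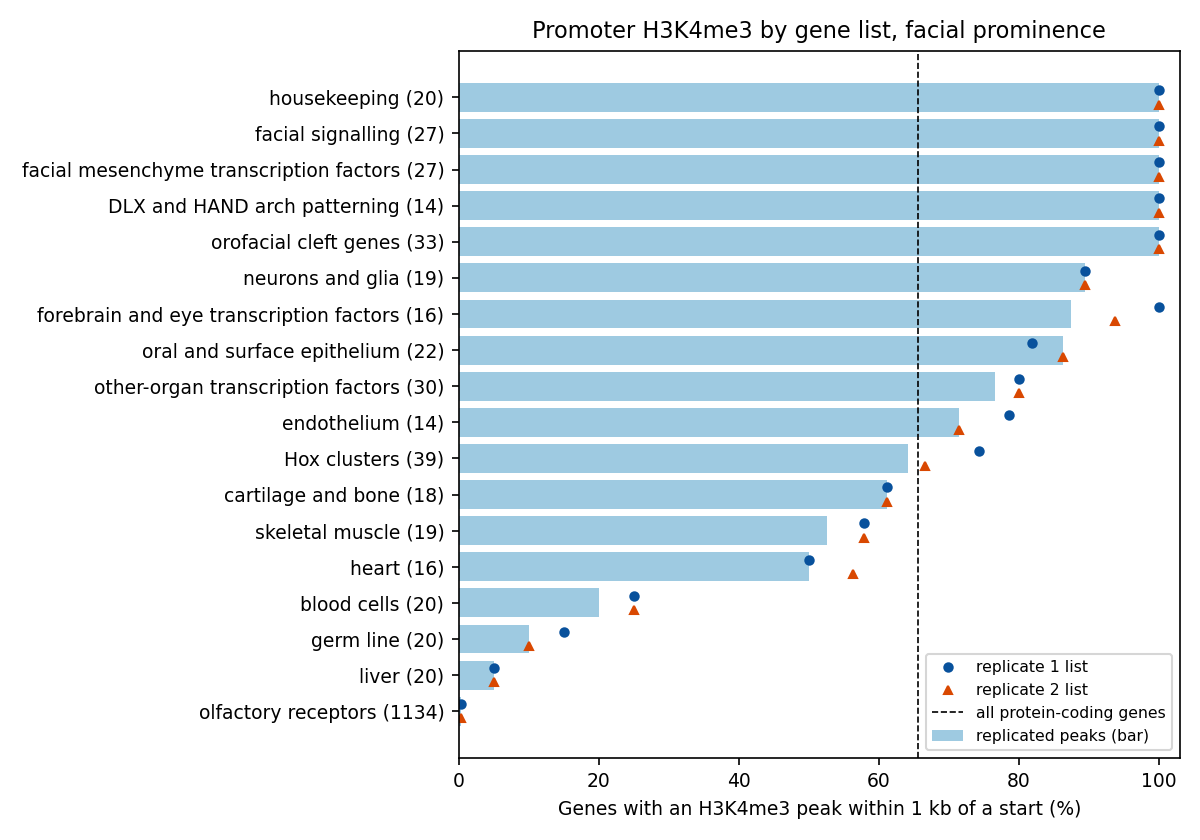
Share of each gene list (x axis, percent of genes) with an H3K4me3 peak within 1000 bp of a start, with list sizes in brackets. Bars give replicated peaks, circles replicate 1, triangles replicate 2, and the dashed line all protein-coding genes (65.6%). The 5 lists at 100% reached it in both replicates, and liver, germ line, blood and olfactory receptor genes lay at or below 25% in both.

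Markers of cell types at the surface of the face or running through it were present in part, and none of these lists passed the test. Oral and surface epithelium had 19 of 22 genes with a peak (86.4%, adjusted exact p = 0.0708). Pitx1, an early marker of the oral ectoderm, had 13071 bp, Sox2 8290 bp, Pitx2 6541 bp and Tfap2c 6277 bp, and Krt15, Krt5 and Lamb3 had none. Neurons and glia had 17 of 19 (89.5%, adjusted exact p = 0.0523), led by Isl1 (6269 bp), Tubb3 (4219 bp), Ascl1 (3865 bp) and Sox10 (3554 bp), without Phox2b and Plp1. By replicate means Neurod1 (3455 bp ± 46.7, SD, n = 2), Gap43 (3454 bp ± 1118, SD, n = 2) and Pou4f1 (3417 bp ± 941, SD, n = 2) stood above Ascl1 (3376 bp ± 24.0, SD, n = 2) and Sox10 (3249 bp ± 121, SD, n = 2). Forebrain and eye transcription factors had 14 of 16 (87.5%, adjusted exact p = 0.105), led by Dmrta2 (10055 bp), Otx1 (9543 bp), Emx2 (8651 bp) and Lhx2 (7917 bp), without replicated peaks at Arx and Tbr1. The order is that of the replicated list and differed in the replicate lists, where Six3 (7071 bp replicated) had the widest mean, with 6655 bp in replicate 1 and 14265 bp in replicate 2, and Emx2 (9657 bp ± 1498, SD, n = 2) stood above Dmrta2 (8637 bp ± 1723, SD, n = 2). Replicate 1 had a peak at all 16, with 248 bp at Arx and 948 bp at Tbr1, and Tbr1 had 266 bp in replicate 2. Against random lists matched on promoter CpG ratio, the share stood at the 98.6th percentile for epithelium and the 97.0th for neurons and glia. For forebrain and eye factors it stood at the 5.57th, below the mean matched share of 96.6%. These 3 lists crossed the threshold under some other settings, such as the pooled list for epithelium (90.9%, adjusted exact p = 0.0311) and for forebrain and eye (100%, adjusted exact p = 0.00467), and the 2500 bp window for neurons and glia (94.7%, adjusted exact p = 0.0118). Endothelium had 10 of 14 (71.4%, adjusted exact p = 0.852), with Fli1 at 7626 bp, Egfl7 at 5102 bp, Esam at 4271 bp and the VEGF receptor gene Kdr at 4096 bp, and without replicated peaks at Emcn, Tek, Tie1 and Vwf. Egfl7 was 4997 bp in replicate 1 and 3376 bp in replicate 2, Esam 4064 and 2271 bp, and Tie1 had 291 bp in replicate 1 only.

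Lists of differentiating tissues were marked in part, and their shares did not pass the test. Cartilage and bone had 11 of 18 genes with a peak (61.1%, adjusted exact p = 0.852). Sox6 (10958 bp), Sox9 (6706 bp), Runx2 (6309 bp) and Col2a1 (4770 bp) had wide domains. The Sox6 domain also reached a start of the neighbouring gene 1110004F10Rik, with a fold enrichment of 34.1 there and 30.5 at Sox6. The bone and hypertrophic cartilage genes Bglap, Col10a1, Dmp1 and Ibsp had no peak. Skeletal muscle had 10 of 19 (52.6%, adjusted exact p = 0.3). Tbx1 (10823 bp), Pax3 (9131 bp), Pax7 (6747 bp) and Tcf21 (3909 bp) had the widest replicated domains, and Acta1, Chrna1, Ckm and Musk had no replicated peak. The replicates differed by over 1.5 times for Tbx1 (10570 and 4464 bp), Pax7 (6919 and 4128 bp) and Tcf21 (2382 and 3607 bp), and by their mean Pax3 was the widest (9274 bp ± 206, SD, n = 2). Acta1 had a domain of 3402 bp in replicate 1 only. With a peak required on the start itself, the muscle share was 36.8% (adjusted exact p = 0.0341). Heart had 8 of 16 (50%, adjusted exact p = 0.272), led by Hcn4 (3053 bp), Nkx2-5 (2847 bp), Tbx5 (2838 bp) and Myl4 (2178 bp), with no replicated peak at Actc1, Mybpc3, Myh6 and Myh7. Tbx5 was 684 bp in replicate 1 and 2697 bp in replicate 2, and the mean of Nkx2-5 (3757 bp ± 566, SD, n = 2) exceeded that of Hcn4 (2910 bp ± 192, SD, n = 2).

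The shares of 4 lists lay below that of other genes and passed the test. Only 1 of 20 liver genes had a peak (5%, adjusted exact p = 1.85e-07), Apoh with 3071 bp, and Afp, Ahsg, Alb and Ambp were among those without. Germ line genes had a peak in 2 of 20 (10%, adjusted exact p = 2.31e-06), Zpbp (1243 bp) and Dazl (914 bp), while Ddx4, Figla, Gdf9 and Mael had none. With the 2500 bp window the shares were 15% for liver (adjusted exact p = 1.74e-05) and 20% for the germ line (adjusted exact p = 0.000105). Blood cell genes had a peak in 4 of 20 (20%, adjusted exact p = 9.91e-05), the erythroid or progenitor genes Tal1 (4453 bp), Epor (3072 bp), Klf1 (1956 bp) and Gypa (1009 bp). Alas2, C1qa and Csf1r had none in either replicate or in the replicated list, and Cd68 had narrow domains of 301 and 269 bp in replicates 1 and 2 but no replicated peak. Each replicate list gave 5 of 20. Of 1134 olfactory receptor genes 3 had a peak (0.265%, adjusted exact p below 1e-300): Olfr94, Olfr1033 and Olfr658. These 4 lists are poor in CpG-rich promoters, with 1 in the liver list, 7 in the germ line list, 1 in the blood list and 0 among olfactory receptors. Against lists matched on promoter CpG ratio, liver stood at the 0.715th percentile and blood at the 45.5th, and no random list was as low as the germ line or olfactory receptor lists. Among CpG-rich genes alone the single liver and the single blood gene each had a peak.

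Domain width separated facial transcription factors from those of other organs, a list of regulators such as Pax2, Tal1, Foxa2 and Hnf4a that define kidney, blood, endoderm and liver. The median width was 9486 bp over the 27 facial genes, with quartiles of 6368.5 and 11410.5 bp, and 1802 bp over the 30 other-organ genes, with quartiles of 546 and 2845 bp. The difference was 7684 bp (permutation test, two-sided, p = 1e-05, the smallest that 100000 permutations can give). It was 7661 bp ± 620 (SD, n = 2) in the replicate lists, more than 10 times the spread between them. Of the other-organ genes 23 had a peak (76.7%, adjusted exact p = 0.3). Pax2 (5436 bp), Tal1 (4453 bp), the lung and thyroid regulator Nkx2-1 (3919 bp) and Neurod1 (3495 bp) had the widest replicated domains, and Crx, Gata1, Hnf1a and Hnf4a had none. The order differed in the replicate lists, where Nkx2-1 (4138 bp ± 407, SD, n = 2) and Nkx2-5 (3757 bp ± 566, SD, n = 2) had the widest means. Pax2 was 2626 and 3945 bp there, and Tal1 2078 and 3322 bp. Promoters were CpG-rich in 24 facial and 19 other-organ genes. With no gap allowed between merged peaks the difference was 4917.5 bp (permutation p = 1e-05).

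**Figure D3:**
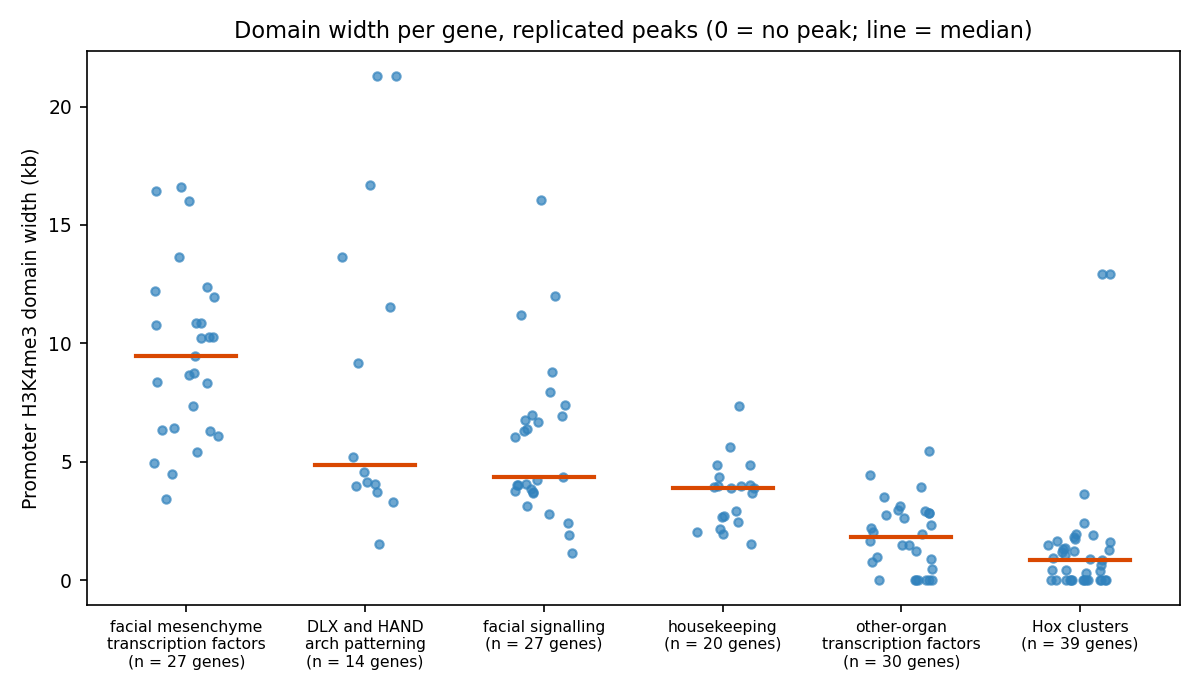
Width of the promoter H3K4me3 domain (y axis, kb) for each gene of 6 lists in the replicated list, with genes without a peak at 0, points spread sideways for visibility and a line at the median. The medians run from 9486 bp for facial mesenchyme transcription factors to 870 bp for Hox genes, whose medians were 703 and 383 bp in the replicate lists, which are not drawn.

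Compared with 10000 random lists matched on promoter CpG ratio, the median width was at or above the 97.5th percentile for 9 of the 18 lists. These were facial mesenchyme factors, arch patterning (4869.5 bp), facial signalling (4344 bp), cleft genes (4033 bp), housekeeping (3888.5 bp), forebrain and eye factors (3789.5 bp), neurons and glia (2566 bp), cartilage and bone (2134.5 bp) and endothelium (2100.5 bp). The Hox genes, with a median of 870 bp, lay below every matched list, whose typical median was 2091 bp. In the replicate lists the Hox median was 703 bp in replicate 1 and 383 bp in replicate 2. The other-organ factors stood at the 43.8th percentile.

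Among the 20 widest domains, that of Nr2f2, an orphan nuclear receptor, came first with 25011 bp at chromosome 7, 70345823 to 70370833, and a replicate width of 20582 bp ± 6160 (SD, n = 2). After the Dlx1 and Dlx2 domain came Ebf3 (19816 bp), Tbx3 (17729 bp), Meis2 (17368 bp), Bahcc1 (16818 bp), Pou3f3, Six1, Tbx2 (16572 bp), Six2, Ptch1, Satb2 and Nr2f1 (15395 bp). The rest were the Polycomb gene Cbx8 (15170 bp), Zfp503 (14596 bp), Meis1 (14325 bp), Tnrc18 (14047 bp), a domain shared by Rhof and the H3K4 methyltransferase gene Setd1b (14045 bp), the H3K27 demethylase gene Kdm6b (13989 bp) and Irx5 (13934 bp). Ebf3 and Tbx2 had nearly the same width in both replicates, with SDs of 38.9 and 27.6 bp (n = 2). Cbx8 was 6948 bp ± 979 (SD, n = 2) in the replicate lists, and Rhof was 13946 bp in replicate 1 and 1843 bp in replicate 2. Setd1b, in the same replicated domain, had a replicate width of 12786 bp ± 1641 (SD, n = 2), so the narrow width in replicate 2 was at Rhof and not at Setd1b. The list of facial mesenchyme factors contributed 3 genes to these domains, arch patterning 3, cleft genes 2 and facial signalling 1, with Ptch1 and Satb2 counted under each list that holds them.

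The Hox clusters, whose genes set position along the body axis, had their widest domain at the 3′ end of HoxA. Of 39 Hox genes 25 had a replicated start peak (64.1%, adjusted exact p = 0.867). Hoxa1 and Hoxa2, the latter the selector gene of the second arch, shared a domain of 12914 bp at chromosome 6, 52157971 to 52170884, with a replicate width of 12889 bp ± 574 (SD, n = 2). The peak at the Hoxa2 start had a fold enrichment of 11.4 and that at the Hoxa1 start 26.9. The next widest were Hoxb2 (3636 bp), Hoxb4 (2435 bp) and Hoxa13 (1935 bp), which was 2580 bp in replicate 1 and 1559 bp in replicate 2. Start peaks were present in 7 of 11 HoxA, 7 of 10 HoxB, 3 of 9 HoxC and 8 of 9 HoxD genes. Genes of paralogue groups 1 to 5 had a peak in 12 of 15 cases and those of groups 6 to 13 in 13 of 24, a difference that did not pass Fisher's exact test (two-sided, p = 0.171). The Hox share was 74.4% in replicate 1, 66.7% in replicate 2 and 84.6% in the pooled list, where it exceeded that of other genes (adjusted exact p = 0.0277).

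Among CpG-rich genes alone, 19 of 28 Hox genes had a peak (67.9%), against 99.0% of the others (adjusted exact p = 1.31e-10). In the pooled list 25 of the 28 had one (89.3%), against 99.2% of the others (Fisher's exact test, two-sided, p = 0.00167). Of the 9 without a replicated peak, Hoxa11, Hoxb8, Hoxc11 and Hoxc12 had no start peak in either replicate. Hoxa3 and Hoxa6 had narrow domains of 255 and 243 bp in replicate 2 only, and Hoxa9, Hoxc9 and Hoxc8 had domains of 226, 216 and 190 bp in replicate 1 only.

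**Figure D4:**
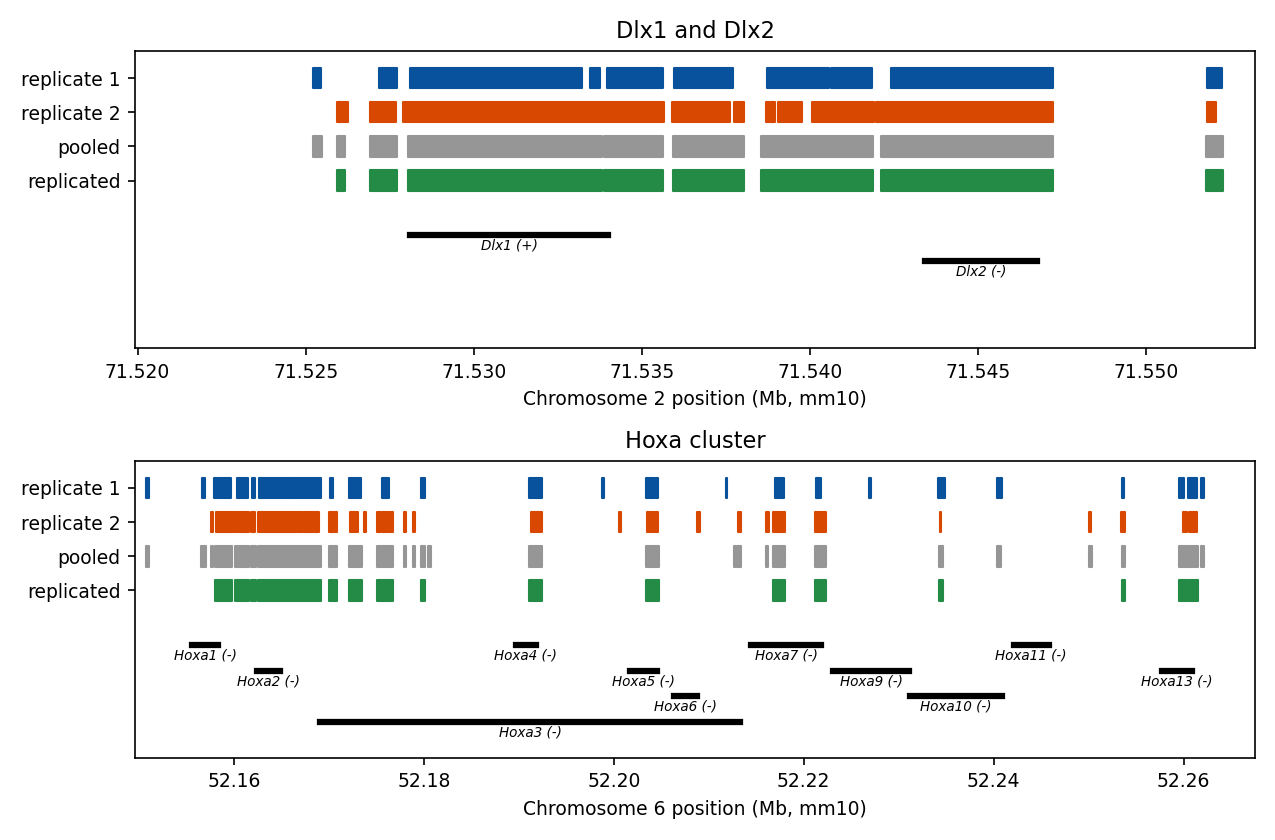
Peaks of the 4 lists (coloured bars) and protein-coding genes (black bars, strand in brackets) at Dlx1 and Dlx2 on chromosome 2 and at the Hoxa cluster on chromosome 6, with positions in Mb on mm10. In the replicated list peaks fill the 21294 bp from Dlx1 to Dlx2 with short gaps, and in replicate 1 a gap above 1000 bp divides them. In the Hoxa cluster they are dense over the 12914 bp of Hoxa1 and Hoxa2 and sparse beyond.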

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

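The gene comparisons used the assembled chromosomes, and 13 replicated peaks lay outside them, on 7 unplaced or unlocalised scaffolds, which is above the 3 that a count of 0 allows. They were 0.0567% of the replicated list. Of these, 4 lay on a scaffold assigned to chromosome X, with a fold enrichment of up to 24.6, and 2 on a scaffold assigned to chromosome 4, with up to 31.8. Replicate 1 had 14 such peaks and replicate 2 had 18.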

How the results depend on the processing

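All alternatives were planned before the data were examined, and where a value moved the cause was not tested unless stated. Each of 230 recomputed values was put in 1 class. Of these, 13 changed direction, among them the liver and blood shares in CpG-rich genes, which also lost their call, and the Hox share in the pooled list, which also gained one. With direction kept, 12 newly passed their threshold, 5 no longer passed, and 30, without a test, moved by more than the spread between replicates or, for counts, by more than 1.5 times. The other 170 kept their direction and side of the threshold or stayed within those limits, which does not mean an equal value. Among these 170, the liver share was 15% and the germ line share 20% with the 2500 bp window, the Hox share 48.7% and the heart share 37.5% with a peak on the start, and 12 lists passed in the pooled list against 9. Adjusted p ranged from 9.31e-08 to 1 for liver and from 2.29e-08 to 0.000105 for the germ line. The share of CpG-rich promoters with a peak stayed between 95.4% and 99.1% under its alternatives. The width difference between facial and other-organ factors stayed between 4917.5 and 9057.5 bp, with a permutation p of 3e-05 at most. No paired analysis was possible because the series holds a single group. Depth is unknown, so it cannot be said how many more weak peaks deeper libraries would give.

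Counting any overlap of 1 bp as shared gave 79.9% of replicate 1 peaks and 75.1% of replicate 2 peaks found, and requiring 50% of both peaks gave 67.8% and 64.0%. Peaks with −log10 q of at least 5 gave 94.2% and 93.0% found, 98.1% of pooled peaks kept, a rho of 0.912, 67.7% of replicated peaks at a start and 65.3% of genes with a peak. Fold enrichment of at least 3 gave 85.1%, 77.7%, 94.8%, a rho of 0.928, 66.2% and 65.4%. A required cover of 50% by the replicate peaks gave a rho of 0.931. The shares of peaks at a start and of genes with a peak were 49.9% and 66.9% in the pooled list, 70.4% and 66.6% with the 2500 bp window, 59.6% and 64.0% with a peak on the start, and 55.9% and 62.9% with the 5′-most start. Each replicate's own list, to which the replication filter was not applied, gave 51.8% to 53.7% of peaks at a start and 66.0% to 66.1% of genes. These shifts also reflect the missing filter and do not measure the influence of a replicate.

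Among the gene lists, the replicates' own peak lists gave 66.7% to 74.4% for Hox genes, above other genes. They gave 93.8% to 100% for forebrain and eye factors and 89.5% in both cases for neurons and glia. These last 2 gene lists were then past the threshold. The pooled list put epithelium (90.9%), Hox genes (84.6%) and forebrain and eye factors (100%) past it and muscle (68.4%) above other genes. The 2500 bp window did so for forebrain and eye (93.8%) and neurons and glia (94.7%), and put cartilage and bone (66.7%) and Hox genes (71.8%) on the other side of the remaining genes without passing. With a peak on the start, muscle (36.8%) passed and endothelium (57.1%) turned lower than other genes. With the 5′-most start, epithelium (86.4%) and neurons and glia (89.5%) passed and endothelium (57.1%) turned lower. Adjusted p ranged over the alternatives from 0.0311 to 1 for epithelium, 0.00452 to 1 for forebrain and eye, 0.0118 to 1 for neurons and glia, 0.0341 to 1 for muscle and 1.31e-10 to 1 for Hox genes.

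Among CpG-rich genes alone 2 lists passed, Hox genes (67.9%) and the germ line (28.6%), both lower. Facial mesenchyme, arch patterning, facial signalling, cleft and housekeeping genes stood at 100% without passing, since the background was then near 100% too. Cartilage and bone, muscle, blood, heart and liver also stood at 100%, above the background and without passing, over between 1 and 6 members each. Olfactory receptors had no CpG-rich member and gave no value.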

Other observations

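The tests of gene families, of weak enrichment in peaks of 1 replicate, of mirrored placement and of the replication filter at Hox genes were chosen after the result was seen. Families were made by a keyword in the RefSeq description, so they can miss members or take in genes that only share the word. Genes with homeobox in the description, called homeobox genes below, were over-represented among the widest domains. A domain of at least 10000 bp was carried by 15 of 221 homeobox genes and by 52 of 20178 other described genes (Fisher's exact test, two-sided, adjusted p = 2.6e-15 over 6 families). In the replicate lists the homeobox counts were 15 and 17 (adjusted exact p = 1.24e-15 and 1.48e-18). In the replicated list they were Barx1, Dlx1, Dlx2, Dlx6, Gsc, Hoxa1, Hoxa2, Irx5, Lhx8, Meis1, Meis2, Msx1, Prrx1, Six1 and Six2, named after their values were seen. Some share a domain, so they are not independent. All but Irx5, Meis1 and Meis2 belong to the facial mesenchyme, arch patterning or Hox lists, so this result overlaps with those of the lists and is not separate from them. Pitx1 (13071 bp), Pou3f3 (16671 bp) and Satb2 (16003 bp) lacked the keyword and were not counted as homeobox genes. Forkhead genes had such a domain in 3 of 48 cases in the replicated list (adjusted exact p = 0.00158), in 2 in replicate 1 (adjusted exact p = 0.0299) and in 1 in replicate 2, against 64 of 20351 other genes there (adjusted exact p = 0.426), so with so few genes the test did not pass in both replicates. Foxd2 (12696 bp) passed that width in each list, Foxf1 (10262 bp), which is in a list fixed beforehand, not in replicate 2, and Foxc1 (11458 bp) in neither replicate. None of 175 genes with ribosomal protein in the description had such a width, although 97.7% had a peak. Nor had any of 275 genes described as mitochondrial, of which 96.4% had a peak. Genes with zinc finger in the description had a peak in 90.7% of 668 cases, and those with keratin anywhere in it in 9.57% of 115. Homeobox genes as a whole had a peak in 66.1% of cases. Outside the Hox clusters, 97.1% of the 104 CpG-rich homeobox genes had one.

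A domain of at least 10000 bp was carried by 68 genes in all. Further examples outside the fixed lists, picked after their values were seen and not tested as a group, were Gata2 (11668 bp), Smad7 (13573 bp), the imprinted growth factor gene Igf2 (11544 bp), the cadherin gene Fat4 (11036 bp) and Lrba (13004 bp), whose domain is shared with Mab21l2.

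Among the 10932 CpG-rich promoters, 116 had no replicated peak: 9 of Hox genes, 5 of the germ line list and 102 others. A near-identical second copy in the genome (at least 95% identity over at least 500 bp) was carried by 53 of the 102 (52.0%), against 0.777% of the 10816 CpG-rich promoters with a peak (Fisher's exact test, two-sided, p = 4.15e-77), so reads that could not be placed in 1 copy may account for these 53. The 53 include sets of genes with related names, such as Tmem254a, Tmem254b and Tmem254c with 2 copies each. Promoters within such sets are not independent, while the p-value treats them as if they were. Among the Hox and germ line genes 0 of 9 and 0 of 5 had such a copy, which argues against long near-identical copies for them. Shorter repeated stretches were not searched, so unplaced reads are not excluded. The authors' replication filter was tested for the Hox genes: 6 of the 9 had a pooled peak, yet the pooled share of 89.3% of CpG-rich Hox genes stayed below the 99.2% of other CpG-rich genes (Fisher's exact test, two-sided, p = 0.00167). Hoxa6, Hoxa9 and Hoxa11 had no pooled peak, so the filter cannot account for these genes. They lie in a single cluster and are not independent, so the p-value is descriptive only. None of the 49 remaining promoters had such a copy. Of these 49, 10 had a pooled peak, and no other explanation was tested for them. The germ line list holds only 20 genes. By name the 49 include relatives of its members, such as Sycp2 beside Sycp1 and Sycp3, picked after the result was seen. Being outside that list therefore does not mean that a gene has no germ line role.

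Facial mesenchyme transcription factors had wider domains than other-organ factors by 2.04 on the log2 scale, or 4.10-fold, among the 27 and 23 genes with a domain. If CpG island extent were the cause, the difference was predicted to vanish after regression on island length within 10000 bp. It stayed at 2.05 (permutation p = 1e-05, the smallest that the permutations can give, here and in the next tests). The regression was linear on the log2 scale and took the islands around a single start per gene, so an effect of island extent that this measure misses is not excluded. After regression on fold enrichment the difference fell to 1.26, or 2.40-fold (permutation p = 1e-05), so peak strength goes with part of the difference and not with all of it. Among 26 and 23 genes whose domain reached no other protein-coding gene's start window it was 2.09 (permutation p = 1e-05), which excludes joining with neighbouring protein-coding starts as the whole cause, while non-coding starts were not examined. That wide domains mark the regulators active in this tissue may be put as a hypothesis. It is untested because expression and other tissues were not analysed here, and read depth stays open. Wide medians were not particular to facial lists. Forebrain and eye factors (3789.5 bp) and housekeeping genes (3888.5 bp) also stood high among lists matched on promoter CpG ratio.

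For peaks seen in 1 replicate only, weak enrichment is a candidate explanation. In replicate 1, 93.6% of the peaks not found in replicate 2 had −log10 q below 5, against 15.0% of those found, a difference of 78.6 percentage points. In replicate 2 the shares were 93.5% and 13.6%. The lists reach down to −log10 q of 0.169 and 0.244, so these shares do not show how near the calling threshold the peaks lay. Another candidate explanation is that a shared region was split at different places. Of the peaks not found in replicate 2, 53.1% lay within 1000 bp of a peak of that replicate, and of those not found in replicate 1, 55.4%. Placed at random, the same peaks gave 4.26% and 3.89%, so they lay near peaks of the other replicate far more often than random placement gives. Mirrored about the nearest shared peak of their own list, they gave 51.1% and 54.5%. Mirroring keeps the distance to that shared peak, so a fragment of a split region would stay near it too. The test therefore cannot tell splitting from clustering around shared peaks, and whether regions were split stays open. A difference between the pools of embryos remains untested.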
